A study of Mus musculus with 60 samples.

How the data were processed

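LAM-HTGTS junctions of CH12F3 cells were analysed in 60 libraries of 12 groups, formed by 4 backgrounds and 3 treatments as the labels give them. Per the submitters' processing notes the positions refer to mm9, and per the labels the libraries were read as paired-end 250 on a MiSeq. The aligner, the junction caller and its filters are not given in the sources used here. The authors deposited, for each library, a headerless list with 1 line per junction, whose start equals its end. The deposited lists also carry a score from 16 to 222 whose meaning is not stated, and it was described but used in no test. Whether positions start at 0 or at 1 is not stated, which matters for no value here. Sequencing runs were read from the read names and are called run 1 to run 6.

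Depth ran from 7419 to 22089 junctions per library outside Lig4-KO and from 35258 to 56900 in Lig4-KO. In a library with 7419 junctions a share is seen in steps of 1 junction, so shares of loci with few junctions are coarse, and a count of 0 allows up to 3 junctions. Of 550507 genome-wide junctions, 4581 (0.832%) lay at 349 positions seen in 10 or more libraries. There were 66 junctions on the mitochondrial genome and 17 on chromosome Y. Replicates correlated with r from 0.329 to 0.726 over windows.

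Run 1 held WT DMSO and WT tazemetostat, run 2 valemetostat in WT and in WT plus idelalisib, and run 3 AID-KO valemetostat with 1 AID-KO DMSO library. Run 4 held the other 4 AID-KO DMSO libraries and AID-KO tazemetostat, run 5 all Lig4-KO libraries, and run 6 WT plus idelalisib with DMSO and tazemetostat.

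From the lists, per-library percents were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The genome-wide share leaves out the bait chromosome and the immunoglobulin loci. The off-target share is the percent of genome-wide junctions in a list of 22 loci written from knowledge, of which 21 lie outside the bait window. All 22 loci stood on the same chromosome and in the same order in a gene table of a later genome build, which was used for names and order only. Groups were compared by two-sided exact permutation tests of the mean percent, with Benjamini-Hochberg adjustment within each set of comparisons and a threshold of 0.05. Intervals are 95% bootstrap intervals from 10000 draws, and interactions are Freedman-Lane permutation tests. With so few libraries per group the intervals can be too narrow. For the genome-wide share with valemetostat in WT the interval ran from 0.293 to 5.35 points, although the exact permutation test gave p = 0.123. Window tallies were tested with limma 3.58.1 (voom) in R 4.3.3, with genome-wide junctions as library size and a mean tally of at least 5 for 1 Mb and 2 for 100 kb windows. Windows of the bait chromosome outside the bait window were tested too, though this library size leaves that chromosome out. AID-KO was left out of the Igh composition, since most of its libraries hold fewer than 10 Igh junctions, a choice made after its counts were seen.

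The methods were tested on simulated data. In simulated WT libraries 200 of 240 windows were changed. There limma voom recovered 67% of windows changed 2-fold and 97% of those changed 4-fold, with 1.20% of calls false. In Lig4-KO, with 200 of 1414 windows changed, these were 61%, 92% and 1.92%. With most WT windows changed, few calls can be false, so the WT figures do not carry over to comparisons with few changes. The exact test called 4.9% of simulated comparisons without a difference and the interaction test 4.6%.

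The groups, shares, tests, the list of loci and the rule for naming windows were set before the data were examined. By that rule the text names Igh and its parts, the listed loci, the 5 called windows with the largest rise and the 5 with the largest fall per comparison, and the 10 AID-dependent windows with the most WT DMSO junctions. Not every window under this rule is printed. Other windows, and which of the listed loci and windows to print, were chosen after their values were seen. Also chosen after the data were seen were the gamma peaks, the test of single AID-dependent windows, the distances of 1 kb and 20 kb around the bait after 1, 5, 20 and 100 kb had been looked at, the within-run values, the depth term, the setting without recurrent positions and all junctions as library size. The depth term was run for all comparisons and then kept only where the depth ranges of the groups overlap. Alternatives also covered identical junctions counted 1 time, another denominator, a logit scale, a cap of 3 junctions per 100 bp, thinning, wider intervals, other window sizes, limma trend, quasi-Poisson regression and each library left out in turn.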

Results

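Linear amplification-mediated high-throughput genome-wide translocation sequencing (LAM-HTGTS) maps the places in the genome to which a fixed broken DNA end, the bait, has been joined. It was applied to CH12F3, a mouse B-lymphoma line that switches its antibody class to IgA when stimulated, after 72 h with anti-CD40, IL-4 and TGF-β. The cells received tazemetostat or valemetostat, both directed at the histone methyltransferase EZH2, or the solvent DMSO. The series asks whether these compounds change chromosomal translocations where activation-induced cytidine deaminase (AID) is very active or where DNA repair is impaired. AID deaminates cytosines in the immunoglobulin heavy chain (Igh) switch regions and, more rarely, at other genes. The 4 backgrounds were unmodified cells (WT), WT cells given the PI3Kδ inhibitor idelalisib (WT plus idelalisib), cells without AID (AID-KO) and cells without DNA ligase 4 (Lig4-KO), the enzyme that seals breaks in classical end joining. The 60 libraries fell into 12 groups. WT had 5 DMSO, 5 tazemetostat and 8 valemetostat libraries, AID-KO had 5, 4 and 3, and WT plus idelalisib and Lig4-KO had 5 of each. The libraries held 1219247 junctions in all, from 7419 to 22089 per library outside Lig4-KO and from 35258 to 56900 in Lig4-KO. Every share given here is a share of the junctions of a library, so it describes where junctions lay and not how many translocations a cell carried. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

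The bait lay on chromosome 15. In the AID-KO DMSO libraries, which lack AID-made breaks, 17625 of 65054 junctions fell into the 10 kb from 61810000 to 61819999 (mm9), and the densest 200 bp ran from 61818800 to 61818999. This place lies in the interval of the Myc-Pvt1 locus, and the 1 Mb on each side of it was set aside as the bait window. Within that window, 60.6% ± 2.27 (SD, n = 5) of the WT DMSO junctions lay within 1 kb of the bait site. The value was 57.1% ± 1.18 (n = 5) with idelalisib, 55.6% ± 1.63 (n = 5) in AID-KO and 40.0% ± 0.976 (n = 5) in Lig4-KO.

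**Figure D1:**
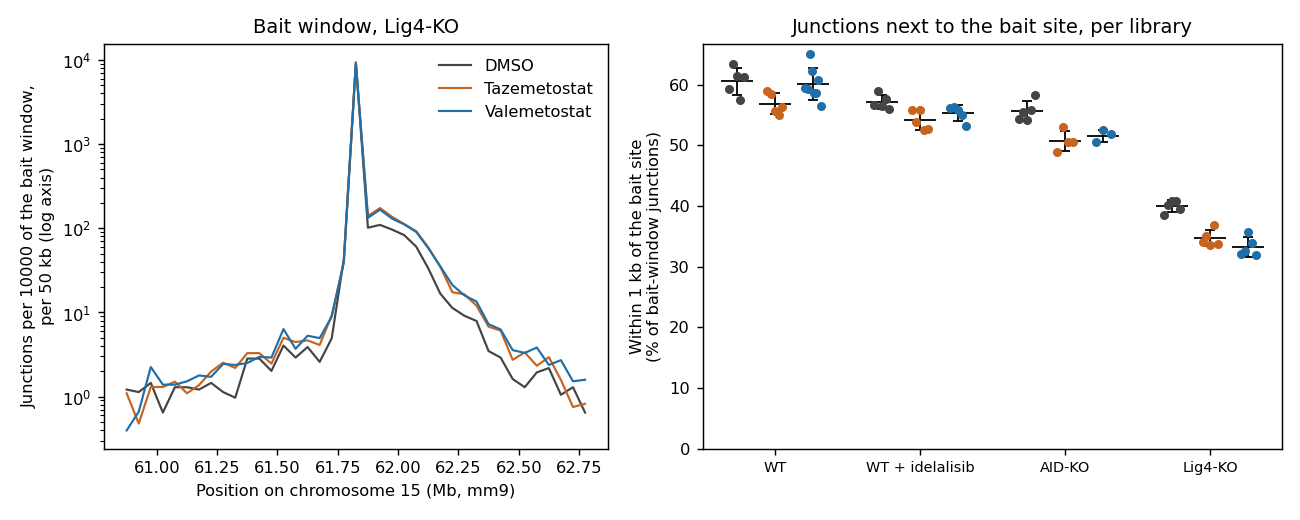
Left, junctions of the bait window per 50 kb of chromosome 15 in the 3 Lig4-KO groups, pooled over libraries and given per 10000 junctions of the window on a log axis. Right, the percent of bait-window junctions within 1 kb of the bait site, with a point per library, the group mean as a line and the SD as the error bar. The Lig4-KO libraries sit lowest, with means of 40.0% in DMSO, 34.7% with tazemetostat and 33.3% with valemetostat.

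Without AID, junctions in the Igh locus nearly vanished, which is the direct check of the AID-KO label. They made up 3.45% ± 0.177 of all junctions in WT DMSO and 0.0379% ± 0.0175 in AID-KO DMSO (n = 5 each). In AID-KO with tazemetostat and valemetostat the Igh share was 0.0160% ± 0.00723 (n = 4) and 0.0366% ± 0.0248 (n = 3), from 9 and 24 Igh junctions in all. Lig4-KO DMSO cells had an Igh share of 1.56% ± 0.0638 (n = 5), 0.453 times that of WT, and WT plus idelalisib had 3.80% ± 0.125 (n = 5), which is 0.348 percentage points above WT. Each of these 3 differences from WT DMSO separated all 5 libraries of a group from all 5 of WT (exact two-sided permutation test, p = 0.00794, the smallest possible, adjusted p = 0.00794). With junctions outside the bait window as the denominator the Igh share of Lig4-KO was 0.783 times that of WT, which was 5.10% ± 0.244. With it the idelalisib difference no longer passed (exact permutation test, adjusted p = 0.103). A depth term, looked at and set aside because the depths of Lig4-KO and WT do not overlap, left a Lig4-KO difference of -1.50 that did not pass (permutation test, p = 0.0699). Backgrounds were sequenced in different runs. AID-KO libraries held 1 to 13 Igh junctions each over 2 runs, whereas for Lig4-KO and idelalisib background and run cannot be told apart.

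Outside the bait chromosome and the immunoglobulin loci, Lig4-KO cells had fewer of their junctions. This genome-wide share was 34.6% ± 1.68 in Lig4-KO DMSO and 60.5% ± 1.17 in WT DMSO (n = 5 each, exact permutation test, adjusted p = 0.0238), with every Lig4-KO library below every WT library. The bait window held 60.8% of Lig4-KO and 32.4% of WT junctions. Among junctions outside it the genome-wide shares were 88.1% ± 0.585 and 89.5% ± 0.343, so most of the gap came from the bait window. Values in AID-KO DMSO and WT plus idelalisib DMSO were 55.2% ± 9.57 and 62.9% ± 1.73 (n = 5 each), with adjusted p of 0.278 and 0.0714 by the same exact test. The AID-KO difference of -5.28 percentage points turned to 4.32 when only junctions outside the bait window were counted in the denominator (exact permutation test, adjusted p = 0.0119). With that denominator Igh held 5.10% in WT DMSO and 0.0652% in AID-KO DMSO, so this rise mirrors the Igh loss and is no separate result. With all junctions as denominator the AID-KO difference passed at -12.9 points with a depth term (permutation test, adjusted p = 0.0138) and at -9.14 without AID-KO DMSO replicate 5. That replicate was the only AID-KO DMSO library of its run and the deepest of its group, with 17692 junctions and a genome-wide share of 70.6%. Depth and run therefore cannot be told apart in these AID-KO values. The idelalisib difference of 2.42 points passed at 3.35 with a depth term (permutation test, adjusted p = 0.0186) and at 3.04 without WT plus idelalisib DMSO replicate 4, and turned to -0.296 with the other denominator. A list of 21 known AID off-target loci outside the bait window, among them Pim1, Cd83, Pax5 and Mir155hg, took 0.466% ± 0.133 of the genome-wide junctions in WT DMSO, 0.267% ± 0.0419 in AID-KO DMSO and 0.883% ± 0.0692 in Lig4-KO DMSO (n = 5 each). Both differences from WT passed the exact permutation test (adjusted p = 0.0238), and the idelalisib group, at 0.541% ± 0.0623 (n = 5), did not (adjusted p = 0.294). For AID-KO the call ended with intervals widened by 50 kb (exact permutation test, adjusted p = 0.107) and without AID-KO DMSO replicate 1, 2, 3 or 5, where the differences were -0.191, -0.198, -0.189 and -0.202. Also, the Lig4-KO and WT libraries did not overlap in depth, where a depth term (looked at and then set aside because of that) left a difference of 0.202 with p = 0.725 by permutation.

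The share of junctions in Igh was lower with both EZH2-directed compounds than with DMSO in WT and Lig4-KO cells. In WT the Igh share fell from 3.45% ± 0.177 in DMSO (n = 5) to 2.74% ± 0.293 with tazemetostat (n = 5) and to 1.37% ± 0.209 with valemetostat (n = 8), which is 0.794 and 0.398 times the DMSO share. In Lig4-KO it fell from 1.56% ± 0.0638 to 1.18% ± 0.0803 and 1.03% ± 0.0513 (n = 5 each), or 0.753 and 0.655 times. In all 4 comparisons every inhibitor library lay below every DMSO library (exact two-sided permutation test over 8 comparisons, adjusted p = 0.0159 for tazemetostat in WT and for both compounds in Lig4-KO, and 0.00622 for valemetostat in WT). With idelalisib the Igh share was 3.80% ± 0.125 in DMSO, 3.69% ± 0.278 with tazemetostat and 3.78% ± 0.192 with valemetostat (n = 5 each, exact permutation test, adjusted p = 0.698 and 0.893). The 95% bootstrap intervals of those idelalisib differences ran from -0.377 to 0.104 and from -0.215 to 0.149 percentage points, which with so few libraries may be too narrow. In AID-KO, where few Igh junctions remained, the adjusted p were 0.0889 and 0.893 (exact permutation test), and the tazemetostat difference passed at -0.0272 points without AID-KO DMSO replicate 4. Within runs the AID-KO differences were -0.0201 points for tazemetostat against 4 DMSO libraries (exact permutation test, p = 0.0857) and -0.00865 for valemetostat against 1. The Lig4-KO libraries shared a run, as did WT DMSO and WT tazemetostat, whereas valemetostat in WT and in WT plus idelalisib was sequenced in a run without a DMSO library. In that run the Igh share was 3.78% with idelalisib and 1.37% in WT (n = 5 and 8, exact permutation test, p = 0.000777), so the WT value was not shared by the whole run. The idelalisib valemetostat difference turned to 0.176 with the denominator outside the bait window and 0.0524 with identical junctions counted 1 time, and that in AID-KO to 0.00187 in the constant region alone.

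**Figure D2:**
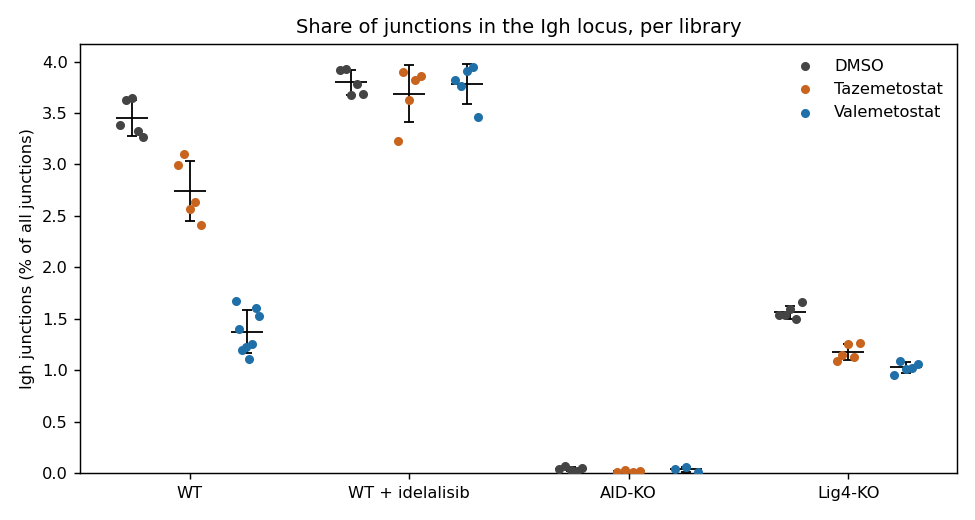
Percent of all junctions that lie in the Igh locus, with a point per library, grouped by background and coloured by treatment. The line and error bar give the mean and SD of each group, and all inhibitor libraries of WT and Lig4-KO lie below the DMSO libraries of the same background.

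The change in the Igh share against DMSO differed between WT plus idelalisib and WT for both compounds, and between Lig4-KO and WT for valemetostat. The valemetostat and DMSO libraries of WT came from separate runs, as did those of WT plus idelalisib. Run or preparation therefore cannot be told apart from background in the valemetostat terms. Relative to WT, the change was smaller by 0.600 percentage points with tazemetostat and by 2.06 with valemetostat when idelalisib was present. It was smaller by 0.687 and 2.07 points in AID-KO, and by 0.322 and 1.54 points in Lig4-KO. Of these 6 interaction terms 5 passed a two-sided Freedman-Lane permutation test with 100000 draws (adjusted p = 0.0139, 2e-05, 0.00167, 2e-05 and, for valemetostat in Lig4-KO, 2e-05, where the unadjusted value of 1e-05 was the smallest the draws allow). The AID-KO share was too low to fall by as many points as in WT, so its 2 terms say little about response. Likewise, the Lig4-KO share of 1.56% could not fall by the 2.08 points seen with valemetostat in WT. The term for tazemetostat in Lig4-KO missed (permutation test, adjusted p = 0.0602), though it passed at 0.386, 0.412 and 0.369 without WT tazemetostat replicate 1, WT tazemetostat replicate 2 or WT DMSO replicate 5. The term for tazemetostat with idelalisib no longer passed at 0.917 with junctions outside the bait window as denominator or at 0.526 after thinning (permutation test, adjusted p = 0.0617 and 0.0574). On the logit scale, which compares proportional changes, the terms with idelalisib were 0.208 and 0.943 and the valemetostat term in Lig4-KO was 0.520 (permutation test, adjusted p = 0.0175, 0.0003 and 0.00045). On that scale the tazemetostat term in Lig4-KO was -0.0483 and that in AID-KO was -0.504, so the direction of both turned, and the valemetostat term in AID-KO no longer passed (permutation test, adjusted p = 0.0657).

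Valemetostat left a lower Igh share than tazemetostat in WT and Lig4-KO. The tazemetostat share was higher by 1.37 percentage points in WT (95% bootstrap interval 1.11 to 1.64, n = 5 and 8, exact permutation test, adjusted p = 0.00311) and by 0.152 points in Lig4-KO (0.0793 to 0.228, n = 5 each, exact permutation test, adjusted p = 0.0159). After thinning every library to 7419 junctions the Lig4-KO difference was 0.0863 and did not pass (exact permutation test, adjusted p = 0.571). With idelalisib the difference was -0.0923 points (-0.371 to 0.160) and in AID-KO -0.0206 points (-0.0423 to 0.00432), with adjusted p of 0.587 and 0.229 by the same exact test. For the genome-wide share the differences were -2.76 (-6.69 to 1.15) in WT, 1.64 (-1.38 to 4.77) with idelalisib, -14.8 (-17.5 to -11.9) in AID-KO and -0.990 (-3.50 to 1.35) in Lig4-KO (exact permutation test, adjusted p = 0.444, 0.492, 0.114 and 0.492). In AID-KO all 4 tazemetostat libraries lay below all 3 valemetostat libraries, and the exact p of 0.0286 is the smallest possible. It could not pass after adjustment unless others did. Its groups were in separate runs. With the denominator outside the bait window the WT genome-wide difference passed at -1.73 (exact permutation test, adjusted p = 0.0186). With it Igh held 4.11% with tazemetostat and 2.01% with valemetostat, so this difference mirrors that in Igh and is no separate result. The doses are not in the labels, so whether they were matched is not known, and only in Lig4-KO did both compounds share a run.

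The part between the mu and alpha switch regions held a larger percent of the Igh junctions with both compounds in WT plus idelalisib and in Lig4-KO. In WT plus idelalisib the part between the mu and alpha switch regions held 13.5% ± 1.55 of Igh junctions in DMSO, 18.8% ± 1.46 with tazemetostat and 20.5% ± 2.41 with valemetostat, and the mu part, at 49.8% ± 1.35 in DMSO, changed by -5.05 and -5.93 percentage points (n = 5 each). In Lig4-KO the part in between rose from 10.7% ± 1.25 to 14.0% ± 0.959 and 15.5% ± 2.46, and the alpha part fell from 51.2% ± 3.36 to 45.2% ± 2.76 with valemetostat (n = 5 each). These passed the exact permutation test over 6 comparisons per part (adjusted p = 0.0159 for the part in between except 0.0238 for tazemetostat in Lig4-KO, 0.0238 for mu with idelalisib, 0.0476 for alpha). Tazemetostat in Lig4-KO left 46.7% ± 2.29 of Igh junctions in the alpha part (n = 5, exact permutation test, adjusted p = 0.143), and no part changed past the threshold in WT, where the part in between held 12.8% ± 0.928 in DMSO, 12.0% ± 2.19 with tazemetostat and 11.1% ± 3.58 with valemetostat (n = 5, 5 and 8, exact permutation test, adjusted p = 0.563 and 0.404). The tazemetostat difference turned to 0.711 after thinning. Whether the composition changed differently between backgrounds was not tested. All are percents of Igh junctions, and in Lig4-KO the Igh share itself fell, so a higher percent there does not show more junctions in that part. After thinning the alpha difference with tazemetostat in Lig4-KO turned to 2.17. Thinning every library to 7419 junctions ended the calls for mu with idelalisib (differences of -2.90 and -5.26 points, exact permutation test, adjusted p = 0.167 and 0.0952), for alpha in Lig4-KO (-6.13, adjusted p = 0.381) and for the part in between with tazemetostat in Lig4-KO (1.73, adjusted p = 0.548). Leaving out WT plus idelalisib DMSO replicate 1, 2 or 3 also ended the tazemetostat call for mu, at -4.81, -4.61 and -5.10 points. The alpha call in Lig4-KO ended with a depth term (-3.60 points, permutation test, adjusted p = 0.526) and without any of valemetostat replicates 1 to 5 (-6.48, -4.85, -6.02, -6.60 and -6.06) or DMSO replicates 3 and 4 (-5.07 and -5.19).

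A set of 3 peaks stood between mu and alpha, picked after the profile was seen, at chromosome 12 positions 114602000, 114574000 and 114551000 (mm9, starts of their densest 1 kb). Their distances from the mu peak, 61 kb, 89 kb and 112 kb, follow the order and lie close to the spacing of the gamma3, gamma1 and gamma2b genes. With idelalisib the gamma1 peak rose from 3.66% ± 1.09 of Igh junctions to 8.59% ± 0.827 with tazemetostat and 8.71% ± 1.70 with valemetostat, and the gamma2b peak rose from 4.57% ± 0.988 to 6.48% ± 0.927 and 7.37% ± 1.32 (n = 5 each). In Lig4-KO the gamma2b peak rose from 2.83% ± 0.470 to 8.08% ± 0.767 and 6.80% ± 0.681 (n = 5 each), and gamma1 stood at 2.64% ± 0.893, 1.93% ± 0.316 and 2.38% ± 0.612. In WT the gamma3 peak fell from 3.58% ± 0.745 to 1.25% ± 0.350 with tazemetostat (n = 5 each) and the gamma2b peak fell from 5.86% ± 0.917 to 3.87% ± 1.05 with valemetostat (n = 5 and 8). All of these rises and falls passed the exact permutation test (adjusted p = 0.0238 for gamma1, 0.0476 for gamma3, and 0.0119 for gamma2b except 0.0190 for tazemetostat with idelalisib). After thinning to 7419 junctions the gamma2b rise with tazemetostat in Lig4-KO was 2.52 points, the gamma2b fall in WT was -1.14 and the gamma3 fall was -2.12, and none passed (exact permutation test, adjusted p = 0.0952, 0.0755 and 0.0952). The gamma3 fall also missed without any of WT tazemetostat replicates 1 to 5 (-2.22, -2.28, -2.41, -2.43 and -2.30). Thinning made a gamma2b rise with tazemetostat in WT pass at 2.27 points (exact permutation test, adjusted p = 0.0357), as did leaving out WT tazemetostat replicate 2 at 1.70, and the gamma3 difference with valemetostat in WT passed at -2.36 without WT valemetostat replicate 2.

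**Figure D3:**
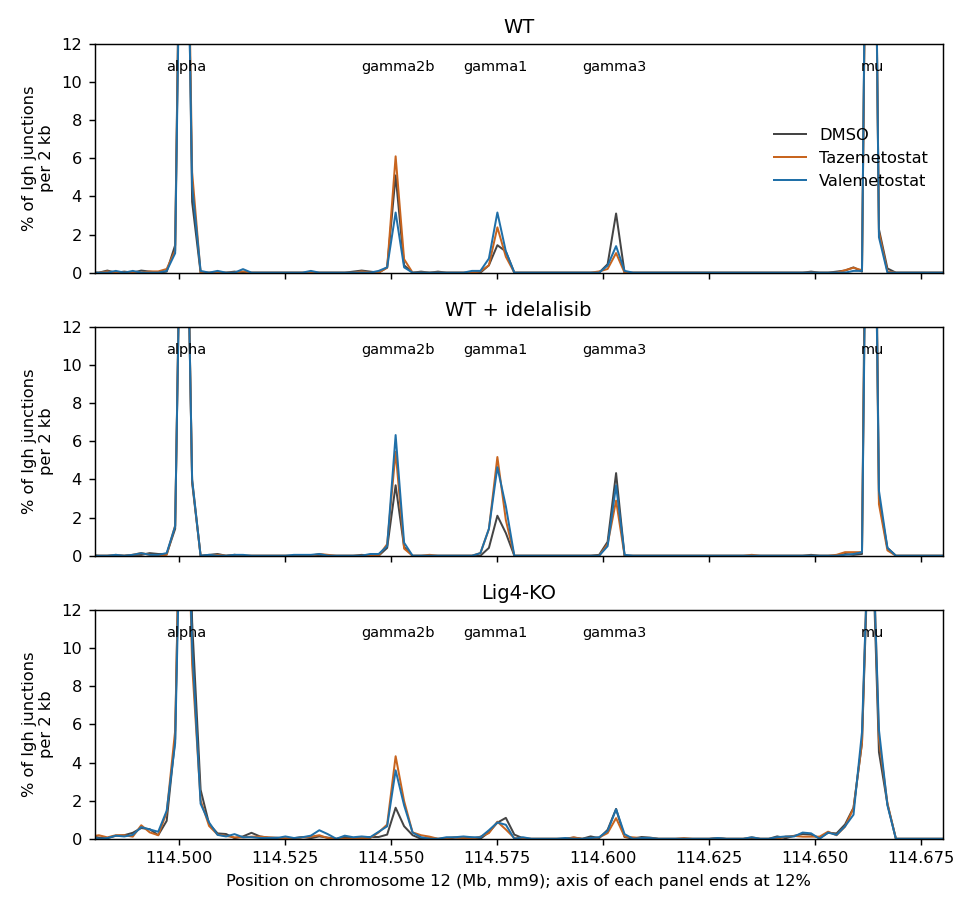
Percent of Igh junctions per 2 kb along chromosome 12 (mm9), pooled over the libraries of a group, for WT, WT plus idelalisib and Lig4-KO. The axis of each panel ends at 12%, so the mu and alpha peaks run off it, and the gamma1 and gamma2b peaks are higher with both inhibitors than in DMSO when idelalisib was given.

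With all junctions as denominator, no difference in the genome-wide share between a compound and DMSO passed after adjustment. In Lig4-KO the share was 34.6% ± 1.68 in DMSO, 31.3% ± 1.82 with tazemetostat and 0.934 times the DMSO share with valemetostat (differences of -3.27 and -2.28 points, 95% intervals -5.19 to -1.31 and -4.48 to 0.188, n = 5 each, exact permutation test over 8 comparisons, p = 0.0238 and 0.127, adjusted p = 0.190 and 0.229). The valemetostat difference turned to 0.242 with the denominator outside the bait window. In WT it was 60.5% ± 1.17, 60.6% ± 3.99 and 63.4% ± 3.65 (n = 5, 5 and 8, adjusted p = 0.960 and 0.229 by the exact test), where the tazemetostat difference of 0.0949 turned to -0.852 with a depth term and -0.0701 after thinning. With idelalisib it was 62.9% ± 1.73, 62.0% ± 3.20 and 60.4% ± 2.24 (n = 5 each, exact test, adjusted p = 0.680 and 0.229). In AID-KO it was 55.2% ± 9.57, 49.4% ± 2.40 and 64.2% ± 2.11 (n = 5, 4 and 3, exact test, adjusted p = 0.402 and 0.229). The AID-KO DMSO libraries came from 2 runs. Within runs the values were 49.4% with tazemetostat against 51.4% ± 4.81 in 4 DMSO libraries (exact permutation test, p = 0.486). With valemetostat the value was 64.2% against 70.6% in replicate 5, the 1 DMSO library of its run, which turns the direction. Counting only junctions outside the bait window in the denominator made the WT valemetostat difference smaller, 2.45 points against 2.85, yet it passed (exact permutation test, adjusted p = 0.00622). With that denominator the Igh share was 5.10% in WT DMSO and 2.01% with valemetostat, so this difference mirrors the Igh fall and is no separate result. The 6 interaction terms of the genome-wide share did not pass (permutation test, adjusted p from 0.105 to 0.698). With the denominator outside the bait window the 3 valemetostat terms did. They were -2.96 with idelalisib, -2.26 in AID-KO, where the direction turned, and -2.21 in Lig4-KO. Each of them subtracts the WT valemetostat difference of 2.45 points, which mirrors the Igh fall, so they are no separate results. With the main denominator the valemetostat terms passed at -6.26 with idelalisib and -6.01 in Lig4-KO without WT valemetostat replicate 2, and at 9.98 in AID-KO without AID-KO DMSO replicate 5.

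Summed over the list, AID off-target loci took a larger part of the genome-wide junctions in Lig4-KO cells given either compound, with 13 of 21 loci higher with tazemetostat and 10 of 21 with valemetostat. The sum rose from 0.883% ± 0.0692 in DMSO to 1.13% ± 0.179 with tazemetostat and 1.06% ± 0.0852 with valemetostat (n = 5 each, exact permutation test over 8 comparisons, adjusted p = 0.0423 for both). In WT they fell from 0.466% ± 0.133 to 0.310% ± 0.0647 with valemetostat (n = 5 and 8, adjusted p = 0.0423 by the exact test) and stood at 0.414% ± 0.0871 with tazemetostat (n = 5, adjusted p = 0.635). Adjusted p lay between 0.159 and 0.992 for idelalisib and AID-KO (exact permutation test). The tazemetostat difference in WT turned to 0.00413 with wider intervals, that with idelalisib to -0.00640 with wider intervals, -0.00501 on the logit scale and -0.0441 after thinning, and the valemetostat difference with idelalisib to 0.00799 after thinning. All 3 calls were narrow. They were lost under 6 alternative settings in Lig4-KO (exact or permutation test, adjusted p from 0.0635 to 0.111), and the WT call was lost under the same 6. The tazemetostat call in Lig4-KO missed without tazemetostat replicate 1, 3 or 5 (0.190, 0.240 and 0.239) or DMSO replicates 1 to 5 (0.247, 0.255, 0.279, 0.234 and 0.242). The valemetostat call in Lig4-KO missed without valemetostat replicate 1, 2, 4 or 5 (0.184, 0.152, 0.168 and 0.195) or DMSO replicate 1, 2, 4 or 5 (0.177, 0.185, 0.163 and 0.171). The WT call missed without valemetostat replicate 2, 3, 4, 6 or 7 (-0.153, -0.151, -0.152, -0.153 and -0.145) or DMSO replicate 1, 2 or 4 (-0.134, -0.159 and -0.113). In AID-KO the tazemetostat difference passed at -0.117 without tazemetostat replicate 1, and within runs the AID-KO differences were -0.0810 for tazemetostat (4 libraries against 4, exact permutation test, p = 0.114) and -0.0627 for valemetostat against 1 library.

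Of single loci in Lig4-KO, none passed when adjusted over the list alone. Pim1, a kinase gene often mutated by AID in lymphoma, had 209 junctions in DMSO, 298 with tazemetostat and 312 with valemetostat. Per 10000 genome-wide junctions this was 42.1 ± 3.71 and 40.2 ± 5.24 with the compounds, 1.40 and 1.34 times the DMSO value (n = 5 each, exact permutation test, p = 0.00794 and 0.0159, adjusted p = 0.111 for both). Mir155hg, the host gene of the microRNA miR-155, had 6.98 ± 1.77 and 14.3 ± 4.79 in DMSO and tazemetostat, and 11.1 with valemetostat. Cd83, a B-cell activation marker, had 10.3 ± 0.957, 14.0 ± 3.21 and 14.4 ± 3.31, and Il4ra-Il21r, which encodes cytokine receptors, had 10.7 ± 3.29, 5.65 ± 1.83 and 7.21 ± 1.36. With valemetostat the differences of Pim1, Cd83 and Mir155hg, 10.2, 4.13 and 4.13 per 10000, were as large together as the rise of the whole list, 0.181 percent of genome-wide junctions. Before adjustment 5 loci were higher and 1 lower with tazemetostat at p under 0.05, and 4 were higher with valemetostat. Between WT DMSO and AID-KO DMSO 0 of 21 loci passed. Pim1 had 6 junctions against 2, Mir155hg 7 against 2 and Cd83 17 against 0 (exact permutation test, p = 0.206, 0.286 and 0.00794, the last with adjusted p = 0.0833). The junctions of Pim1 and Mir155hg are therefore not shown here to depend on AID. In WT, Cd74, the invariant chain of MHC class II, fell from 6.55 ± 2.10 to 1.11 ± 0.961 per 10000 with valemetostat (n = 5 and 8, exact permutation test, adjusted p = 0.0163 over the list), from 21 and 6 junctions in separate runs. With tazemetostat, in the run of WT DMSO, it was 2.07 ± 1.87 from 7 junctions (n = 5, exact permutation test, adjusted p = 0.167 over the list).

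Windows picked from the data as AID-dependent gave a similar reading in Lig4-KO. Of 30 tested windows of 100 kb, 19 had more junctions in WT DMSO than in AID-KO DMSO and 2 had fewer (limma voom), and 16 of the 19 lay outside Igh. The windows outside Igh with the most WT DMSO junctions were on chromosome 15 at 74700000 (57 junctions against 1 in AID-KO DMSO), chromosome 14 at 32400000 (45 against 2), chromosome 8 at 97200000 (41 against 5) and chromosome 12 at 81200000 (39 against 1). The window at 74700000 lies on the bait chromosome. In Lig4-KO it held the most junctions of the 16 and so weighs most in their sum (556 in DMSO, 796 with tazemetostat and 872 with valemetostat). Together the 16 windows rose in Lig4-KO from 1.06% ± 0.115 of all junctions in DMSO to 1.28% ± 0.0689 with tazemetostat and 1.26% ± 0.102 with valemetostat (n = 5 each, exact permutation test over 4 comparisons, adjusted p = 0.0476 for both). With idelalisib they held 1.03% ± 0.0984, 1.07% ± 0.121 and 1.01% ± 0.0606 (n = 5 each, exact test, adjusted p = 0.675 for both), where the tazemetostat difference turned to -0.0427 with 1 Mb windows and -0.00270 after thinning, and the valemetostat difference to 0.0209 with the other denominator. The Lig4-KO calls were also narrow: a cap of 3 junctions per 100 bp, identical junctions counted once, the other denominator and a depth term each ended them (exact or permutation test, adjusted p from 0.0635 to 0.220), and 1 Mb windows ended the tazemetostat call (0.140 points, exact test, adjusted p = 0.0794). The valemetostat call also ended without valemetostat replicate 1, 2, 4 or 5 (0.192, 0.161, 0.211 and 0.198) or DMSO replicate 1, 2, 4 or 5 (0.210, 0.176, 0.165 and 0.204).

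Of these 16 windows tested singly in Lig4-KO, 7 rose with tazemetostat and 3 with valemetostat, and none fell (limma voom). This test was added after the data were seen. The window at 23600000 of chromosome 13 rose by 0.86 ± 0.19 (log2, SE) with tazemetostat and 0.84 ± 0.19 with valemetostat (limma adjusted p = 0.000175 and 0.000389), from 82 junctions in DMSO to 153 and 161. The window at 56500000 of chromosome 12 rose by 0.72 ± 0.16 and 0.68 ± 0.16 (limma adjusted p = 0.000175 and 0.000439), and that at 74700000 of chromosome 15 by 0.52 ± 0.16 and 0.53 ± 0.16 (0.00722 and 0.00786). The latter lies on the bait chromosome, which the library size leaves out. Without Lig4-KO DMSO replicate 2 the tazemetostat count was 3, with all junctions as library size it was 4, and without Lig4-KO valemetostat replicate 3 the valemetostat count was 6. With idelalisib no window passed for either compound (limma voom; 1 and 0 windows at an unadjusted p under 0.05). The test was first run in WT and AID-KO as well. There it gave 1 lower window for tazemetostat and 9 for valemetostat in WT, 0 and 1 in AID-KO, and 0 higher ones, and these counts were set aside because the DMSO libraries of both backgrounds had chosen the windows.

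**Figure D4:**
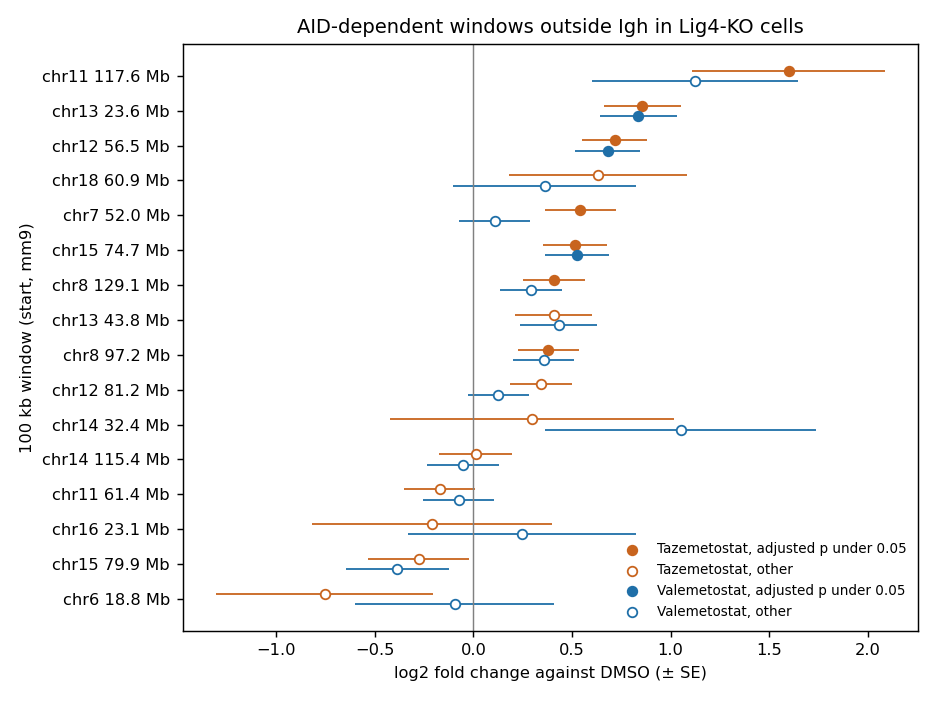
Fitted log2 fold change against DMSO, with its SE, of the 16 AID-dependent windows of 100 kb outside Igh in Lig4-KO cells, ordered by the tazemetostat value. Filled points have a limma adjusted p under 0.05, which holds for 7 windows with tazemetostat and 3 with valemetostat, all above 0.

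Across the genome in 1 Mb windows, few places changed with the compounds. In Lig4-KO, 6 of 1465 windows rose and 2 fell with tazemetostat, and 3 rose and 1 fell with valemetostat (limma voom). Among the rises were windows of the bait chromosome, from 31000000 and 82000000 with tazemetostat and from 74000000 with valemetostat. The library size leaves that chromosome out. The window of chromosome 13 from 23000000 rose by 0.87 ± 0.13 and 0.70 ± 0.13 (log2, SE; limma adjusted p = 1.19e-06 and 0.000426), and that of chromosome 12 from 56000000 by 0.67 ± 0.14 and 0.65 ± 0.14 (0.00213 and 0.00358). The Igh window of chromosome 12 from 114000000 fell by 0.26 ± 0.06 and fell by 0.51 ± 0.06 in Lig4-KO (0.00953 and 9.58e-10) and fell by 1.43 ± 0.12 with valemetostat in WT (9.4e-15). A quasi-Poisson regression gave 0 windows for both Lig4-KO comparisons, and windows of 5 Mb gave 4 for tazemetostat. With all junctions as library size valemetostat gave 7. The tazemetostat count of 8 was 4 without Lig4-KO DMSO replicate 5, and the valemetostat count of 4 was 2 without Lig4-KO DMSO replicate 2 and 7 without Lig4-KO valemetostat replicate 3. Valemetostat in WT gave 2 higher and 5 lower windows of 166, and with idelalisib 1 higher and 0 lower of 277. In WT the higher ones lay near the bait, from 59000000 and 60000000 of chromosome 15. Besides Igh, the lower ones started at 32000000 of chromosome 14, 117000000 of chromosome 11, 79000000 of chromosome 15 and 125000000 of chromosome 8. All of these but the last hold windows of the AID-dependent set. The same WT DMSO libraries had chosen that set, and the run was separate. The idelalisib count was 0 without WT plus idelalisib DMSO replicate 5 and 0 in windows of 5 Mb. Tazemetostat gave 0 of 166 in WT, 0 of 277 with idelalisib and 0 of 560 in AID-KO, where valemetostat also gave 0 (limma voom; 16, 19, 32 and 51 windows at an unadjusted p under 0.05). Without the filter on low tallies each compound gave 1 window in AID-KO.

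Between backgrounds in DMSO, Lig4-KO had 24 windows higher and 14 lower than WT of 533 (limma voom), with libraries deeper than those of WT. The window of chromosome 17 from 29000000, which holds Pim1, was higher by 2.12 ± 0.29 (log2, SE; limma adjusted p = 4.58e-08) and that of chromosome 15 from 74000000 by 1.97 ± 0.18 (8.29e-14). The latter lies on the bait chromosome, which the library size leaves out. In AID-KO 1 window was higher and 10 lower, led by the Igh window, which fell by 6.76 ± 0.32 (1.83e-28), and with idelalisib 2 were higher and 0 lower. With all junctions as library size the Lig4-KO count of 38 was 253, of which 242 were lower, and it was 20 with limma trend, 21 by quasi-Poisson regression and 22 without the filter on low tallies. The AID-KO count of 11 was 4 without AID-KO DMSO replicate 5, 20 with limma trend and 3 by quasi-Poisson regression. The idelalisib count was 1 without WT DMSO replicate 1 or WT plus idelalisib DMSO replicate 4, 0 without WT DMSO replicate 4 or 5, 0 by quasi-Poisson regression and 0 in windows of 5 Mb.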

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

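The tests in this part, including the splits of libraries and those of the 3 patterns, were chosen only after the results were seen. In 4 of 82 groups by measure (8 measures), the highest library lay far from its group, where chance flags about 1 in 20 groups. WT DMSO replicate 4 had 11953 junctions (others 9946 to 10353) and WT plus idelalisib valemetostat replicate 5 had 19186 (others 9294 to 10489). The AID-dependent share was 1.28% in WT plus idelalisib tazemetostat replicate 2 (others 0.983% to 1.07%). The part of Igh between mu and alpha was 24.7% in WT plus idelalisib valemetostat replicate 5 (highest of the others 20.3%).

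The interaction tests flagged 5 differences between backgrounds in the change of the Igh share against that in WT, in percentage points: 0.600 (tazemetostat) and 2.06 (valemetostat) with idelalisib, 0.687 and 2.07 in AID-KO, and 1.54 (valemetostat) in Lig4-KO. In AID-KO the share was near 0, so its 2 terms say little, and in Lig4-KO the starting share of 1.56% was below the loss seen with valemetostat in WT. All valemetostat terms rest on WT groups from separate runs.

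Lig4-KO cells given either compound had a lower Igh share and a higher share of AID-dependent windows. Library depth does not account for the Igh fall, with a larger permutation p of 5e-05 with a depth term. The lists held no repeated lines in Igh, so counting identical junctions 1 time changed the denominator alone. The smaller fall was then -0.526 points, which is no test of repeats in Igh. Lower AID activity at all targets would lower the other windows as well, if AID made their breaks in Lig4-KO too. The smaller difference there was 0.198, a call that many alternatives ended. No Lig4-KO group lacked AID, so the difference cannot decide this. The window at 32400000 of chromosome 14, chosen with 45 junctions against 2, held only 2, 3 and 8 in the Lig4-KO groups. Whether fewer Igh breaks, their joining within Igh or another step lies behind the Igh fall stays open.

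The Igh share was lower with valemetostat in WT. An effect of the whole run is argued against by WT plus idelalisib valemetostat, at 3.78% in that run, and depth by an adjusted difference of -2.10. WT valemetostat and WT DMSO shared 0 runs, so a difference in culture or library preparation of this group cannot be told apart from the compound.

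In Lig4-KO, junctions lay farther from the bait with either compound. For the share more than 20 kb above the bait, depth is argued against by a larger permutation p of 0.00015 with a depth term. With identical junctions counted 1 time the smaller rise was 5.39 points. Separate junctions crowded next to the bait can share a position, so this setting cuts the counts there most. It therefore cannot decide whether repeated lines matter. Breaks made by AID near the bait are argued against by the share within 1 kb, which changed by -4.23 points in AID-KO with tazemetostat in 1 run. For breaks made by AID more than 20 kb above, the share there differed by 0.605 points in the same libraries (exact permutation test, p = 0.0571), so they cannot be told apart from other causes, and AID-KO is another background. The cause stays open.

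Libraries of the compared groups were also split at random into sets of the same sizes, 100 times at most, and the number of splits with at least as many calls, the highest count of any other split and the real count were recorded, only to see whether chance can be excluded. For 1 Mb windows these were 100, 1 and 0 for tazemetostat in WT, 1, 3 and 7 for valemetostat in WT, 100, 1 and 0 and 3, 1 and 1 for the compounds with idelalisib, 100, 2 and 0 and (of 56 splits) 56, 3 and 0 in AID-KO, and 1, 7 and 8 and 1, 1 and 4 in Lig4-KO. For backgrounds they were 1, 1 and 2 with idelalisib, 1, 4 and 11 in AID-KO and 1, 10 and 38 in Lig4-KO, and for the AID-dependent windows 1, 4 and 21. For single AID-dependent windows they were 100, 2 and 0 for each compound with idelalisib, and 3, 7 and 7 and 4, 4 and 3 in Lig4-KO, where another split reached as many calls or more.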

How the results depend on the processing

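The depth term, recurrent positions, all junctions as library size, within-run values, peaks, single windows and bait distances were chosen after the data were seen. The 4 falls of the Igh share in WT and Lig4-KO kept direction and call under every alternative that was tested. The cap, the setting without recurrent positions and identical junctions counted 1 time leave Igh junctions untouched. They change only the denominator, so they say little about these falls. Without leaving libraries out, 818 values stayed the same, 22 moved, 27 reversed, 46 weakened and 7 became significant; with 1 library left out at a time these were 1254, 11, 40, 83 and 12. The cause was not tested for any of them. In AID-KO only 1 to 13 Igh junctions per library remained, which limits what its Igh share can show.

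Taz and Val stand for tazemetostat and valemetostat against DMSO, term for an interaction, compounds for tazemetostat minus valemetostat. 1 Mb windows for the AID-dependent set gave: AID-dependent share (idelalisib Taz -0.0427, Lig4-KO Taz 0.140), AID-dependent windows (8). 5 Mb windows gave: changed windows (idelalisib Val 0, Lig4-KO Taz 4, idelalisib background 0). All junctions as library size gave: changed windows (Lig4-KO Val 7, Lig4-KO background 253), single windows (Lig4-KO Taz 4). At most 3 junctions per 100 bp gave: off-target loci (WT Val -0.156, Lig4-KO Taz 0.223, Lig4-KO Val 0.156), AID-dependent share (Lig4-KO Taz 0.167, Lig4-KO Val 0.154). The Igh constant region only gave: Igh (AID-KO Val 0.00187). The denominator outside the bait window gave: genome-wide (WT Val 2.45, Lig4-KO Val 0.242, idelalisib background -0.296, AID-KO background 4.32, WT compounds -1.73, Val term idelalisib -2.96, Val term AID-KO -2.26, Val term Lig4-KO -2.21), Igh (idelalisib Val 0.176, idelalisib background 0.285, Taz term idelalisib 0.917), AID-dependent share (idelalisib Val 0.0209, Lig4-KO Taz 0.885, Lig4-KO Val 0.750). Genome-wide and Igh junctions are parts of the same total there, so a lower Igh share raises the genome-wide share. Identical junctions counted 1 time gave: Igh (idelalisib Val 0.0524), AID-dependent share (Lig4-KO Taz 0.354, Lig4-KO Val 0.315), within 1 kb (WT Taz -3.50). Intervals widened by 50 kb gave: off-target loci (WT Taz 0.00413, WT Val -0.130, idelalisib Taz -0.00640, Lig4-KO Taz 0.284, Lig4-KO Val 0.191, AID-KO background -0.167). Limma trend gave: changed windows (AID-KO background 20, Lig4-KO background 20). The depth term gave: genome-wide (WT Taz -0.852, idelalisib background 3.35, AID-KO background -12.9), off-target loci (WT Val -0.144, Lig4-KO Taz 0.280, Lig4-KO Val 0.202), AID-dependent share (Lig4-KO Taz 0.218, Lig4-KO Val 0.169), mu (Lig4-KO Taz -0.0219, Lig4-KO Val -0.697), alpha (Lig4-KO Val -3.60), beyond 20 kb (AID-KO Taz 0.551). The logit scale gave: off-target loci (WT Val -0.384, idelalisib Taz -0.00501, Lig4-KO Taz 0.245, Lig4-KO Val 0.187), Igh (Taz term AID-KO -0.504, Val term AID-KO 0.751, Taz term Lig4-KO -0.0483). No filter on low tallies gave: changed windows (AID-KO Taz 1, AID-KO Val 1, Lig4-KO background 22). Quasi-Poisson regression gave: changed windows (Lig4-KO Taz 0, Lig4-KO Val 0, idelalisib background 0, AID-KO background 3, Lig4-KO background 21). Recurrent positions left out gave: off-target loci (WT Val -0.158, Lig4-KO Taz 0.256, Lig4-KO Val 0.183). Thinning to the smallest library gave: genome-wide (WT Taz -0.0701), off-target loci (WT Val -0.142, idelalisib Taz -0.0441, idelalisib Val 0.00799, Lig4-KO Taz 0.364, Lig4-KO Val 0.306), AID-dependent share (idelalisib Taz -0.00270), mu (WT Val -0.983, idelalisib Taz -2.90, idelalisib Val -5.26, Lig4-KO Taz -1.75, Lig4-KO Val -0.194), alpha (Lig4-KO Taz 2.17, Lig4-KO Val -6.13), between (WT Taz 0.711, Lig4-KO Taz 1.73), gamma3 (WT Taz -2.12), gamma2b (WT Taz 2.27, WT Val -1.14, Lig4-KO Taz 2.52), within 1 kb (WT Taz -3.87, idelalisib Taz -2.39, idelalisib Val -1.51), Igh (Lig4-KO compounds 0.0863, Taz term idelalisib 0.526).

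With the replicate number as a replicate block (paired libraries) the values were: within 1 kb (WT Val 0.385), changed windows (WT Val 4, Lig4-KO Taz 17, Lig4-KO Val 9, AID-KO background 18), single windows (Lig4-KO Val 5). Correlations of libraries with the same number ran from -0.150 to 0.128. They give little sign that the numbers pair libraries, but with few junctions per window they cannot exclude it. For shares the block is a value with no test, a choice made after its p-values were seen, since so few pairs cannot pass the threshold.

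With 1 library left out at a time, the lowest and highest values were: genome-wide (WT Taz -0.977 to 1.47, idelalisib background 1.96 to 3.04, AID-KO background -9.14 to -2.65, Taz term idelalisib -2.35 to 0.0964, Val term idelalisib -6.29 to -4.66, Val term AID-KO 3.49 to 9.98, Val term Lig4-KO -6.05 to -4.42), Igh (idelalisib Taz -0.162 to 0.00563, idelalisib Val -0.0585 to 0.0631, AID-KO Taz -0.0272 to -0.0157, AID-KO Val -0.0125 to 0.0120, idelalisib compounds -0.172 to 0.0226, Taz term Lig4-KO 0.239 to 0.412), off-target loci (WT Val -0.190 to -0.113, idelalisib Taz -0.0358 to 0.0361, idelalisib Val -0.0495 to 0.0226, AID-KO Taz -0.117 to -0.0682, Lig4-KO Taz 0.190 to 0.303, Lig4-KO Val 0.152 to 0.209, AID-KO background -0.233 to -0.155), AID-dependent share (idelalisib Taz -0.0127 to 0.0625, idelalisib Val -0.0549 to 0.00165, Lig4-KO Val 0.161 to 0.238), mu (idelalisib Taz -5.68 to -4.37), alpha (idelalisib Taz -0.931 to 0.168, idelalisib Val -1.84 to 0.394, Lig4-KO Val -6.87 to -4.85), between (WT Taz -1.40 to 0.0740), gamma3 (WT Taz -2.66 to -2.20, WT Val -2.36 to -1.41, Lig4-KO Val -0.153 to 0.309), gamma2b (WT Taz 0.667 to 1.70), within 1 kb (WT Taz -4.46 to -2.97, WT Val -1.25 to 0.246, idelalisib Val -2.10 to -1.29, AID-KO Val -4.44 to -3.36), beyond 20 kb (WT Val -0.00629 to 0.177, idelalisib Val -0.0403 to 0.289, AID-KO Taz 0.503 to 0.707, AID-KO Val 0.619 to 0.861), changed windows (idelalisib Val 0 to 1, Lig4-KO Val 2 to 7, Lig4-KO Taz 4 to 12, AID-KO background 4 to 15, idelalisib background 0 to 3), single windows (Lig4-KO Taz 3 to 9, Lig4-KO Val 3 to 6).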

Other observations

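All tests in this part were chosen only after the results were seen, and the distances were picked from 4 that were looked at. In Lig4-KO cells both compounds moved junctions away from the bait. The share of bait-window junctions within 1 kb of the bait site fell from 40.0% ± 0.976 to 34.7% ± 1.32 with tazemetostat and 33.3% ± 1.58 with valemetostat, and the share more than 20 kb above it rose from 5.95% ± 0.261 to 8.79% ± 0.288 and 8.67% ± 0.495 (n = 5 each, 1 run). Every inhibitor library lay beyond every DMSO library (exact permutation test, adjusted p = 0.0159 and 0.0317). Of the junctions more than 20 kb above, 80.2%, 83.2% and 83.2% were on the plus strand. Lig4-KO DMSO cells already had more of them than WT DMSO cells (5.95% against 2.94% ± 0.351, n = 5 each, exact permutation test, adjusted p = 0.0238, separate runs).

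The share within 1 kb also fell with tazemetostat in WT (60.6% ± 2.27 to 56.9% ± 1.76, n = 5 each), with tazemetostat and valemetostat in WT plus idelalisib (57.1% ± 1.18 to 54.1% ± 1.61 and 55.3% ± 1.25, n = 5 each) and in AID-KO (55.6% ± 1.63 to 50.7% ± 1.69 and 51.6% ± 0.976, n = 5, 4 and 3), by exact permutation tests (adjusted p = 0.0363, 0.0159, 0.0363, 0.0159 and 0.0286). With valemetostat in WT it was 60.1% ± 2.59 (n = 8, exact permutation test, adjusted p = 0.752). More than 20 kb above the bait, AID-KO rose from 2.99% ± 0.228 to 3.57% ± 0.278 and 3.73% ± 0.242 (exact permutation test, adjusted p = 0.0476 for both), which within runs was a difference of 0.605 with p = 0.0571 for tazemetostat and 0.661 against 1 library for valemetostat. As a share of all junctions neither AID-KO difference passed, at 0.449 for tazemetostat, and that for valemetostat turned to -0.0532 (exact permutation test, adjusted p = 0.127 and 0.857). Thinning ended the calls within 1 kb for tazemetostat in WT (-3.87) and both compounds with idelalisib (-2.39 and -1.51). Within runs the AID-KO differences within 1 kb were -4.23 for tazemetostat (4 libraries against 4, exact permutation test, p = 0.0286, the smallest possible) and -6.66 for valemetostat against 1 library. Leaving out 1 library ended the calls beyond 20 kb in AID-KO for 8 of 9 libraries with tazemetostat and for all 8 with valemetostat, and those within 1 kb for tazemetostat in WT (6 of 10), valemetostat with idelalisib (7 of 10) and valemetostat in AID-KO (3 of 8).

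Within 1, 5, 20 and 100 kb the share was lower at an unadjusted p under 0.05 in 7, 6, 5 and 4 of 8 comparisons, and the share beyond these distances above the bait was higher in 5, 4, 4 and 3. Above 1 kb it was lower with valemetostat in WT, by a difference of -2.58 points (exact permutation test, p = 0.0373). With valemetostat in WT, the share of mu-part junctions on the plus strand was higher by 12.4 percentage points than the 49.7% ± 3.53 in DMSO (n = 8 and 5, exact permutation test, adjusted p = 0.00466, separate runs), and the other 5 mu comparisons did not pass. Of 6 alpha comparisons 1 passed, a difference in the plus-strand share of -9.18 points in Lig4-KO with tazemetostat (n = 5 each, shared run, exact permutation test, adjusted p = 0.0476). The share more than 20 kb below the bait rose in WT from 0.673% ± 0.118 to 0.864% ± 0.0722 with tazemetostat and 1.23% ± 0.307 with valemetostat (n = 5, 5 and 8, exact permutation test, adjusted p = 0.0317 and 0.0311, with valemetostat in a separate run). In Lig4-KO it was 0.781% ± 0.0476 in DMSO and 0.896% ± 0.0480 with tazemetostat (n = 5 each, exact permutation test, adjusted p = 0.0423), but a depth term reduced the difference of 0.115 to 0.0700 and ended the call (permutation test, unadjusted p = 0.0508). The valemetostat difference of 0.116 did not pass (exact permutation test, adjusted p = 0.140) and was 0.0345 with a depth term (permutation test, unadjusted p = 0.477).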
